A study of Mus musculus with 3 samples.

How the data were processed

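Liver cells of male C57BL/6 mice that lack Ifih1, the gene of the double-stranded RNA sensor MDA5, and carry the hepatocyte-specific Alb-Cre transgene were profiled by droplet single-cell RNA sequencing with the 10x Genomics 3' kit. The 3 libraries differ in Adar1 genotype: wt/wt, wt/flox and flox/flox, with 1 library each. Per the labels' protocols, livers were perfused with collagenase, the cell suspension was spun at low speed, red blood cells were lysed, and live cells were collected on a Percoll gradient, steps that favour hepatocytes and set part of the cell class shares. The deposited values are UMI counts per gene and barcode as whole numbers, and per the file headers they were written by Cell Ranger 6.1.1. The submitters' processing notes also name Seurat and the mm10 genome build, and state no scaling of the deposited counts. Each library holds exactly 10000 barcodes with a sharp lower edge at 727, 721 and 636 UMIs for wt/wt, wt/flox and flox/flox, so that barcodes were chosen by number before deposit. Whether reads were downsampled when the 3 libraries were combined is not stated. The number after the hyphen in each barcode gives the library. Between pairs of libraries 20, 32 and 27 barcodes shared a sequence.

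Total depth was 9744380 UMIs for wt/wt, 10067929 for wt/flox and 10756790 for flox/flox. Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 40% of UMIs from mitochondrial genes, which left 9878, 9920 and 9772 barcodes. The UMI minimum removed 0 barcodes, since the deposited edge lies above it. Doublets were searched with the Scrublet method of scanpy at an expected rate of 0.08. It called 0 barcodes in each library and is taken as not having worked, so all barcodes were kept and doublets remain in the data.

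Kept barcodes were scaled to 10000 counts, log-transformed and clustered together in scanpy 1.11.5 under Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0), with 2000 variable genes, 30 components, 15 neighbours and the Leiden method at resolution 1, and without integration of the libraries. A cluster was named X-like when at least 3 markers of that class, fixed before the data were examined, were at least 4-fold above the other barcodes and detected in at least 5% of its barcodes, and at least 1 was among its 10 leading genes by fold. These thresholds were set with the data in hand. A cluster with no such class was called hepatocyte-like when it held hepatocyte markers, no other class had markers among its 10 leading genes and none had 3 at 4-fold. Barcodes of this class cannot be separated from droplets of free hepatocyte RNA, since nearly every cluster carried the 12 hepatocyte markers in at least 50% of its barcodes. Cluster 19, with 91 barcodes led by mitotic genes, stayed unnamed. It held 0.182%, 0.383% and 0.358% of barcodes in wt/wt, wt/flox and flox/flox. The Kupffer-like and the monocyte or macrophage-like cluster were also pooled as macrophage-like. Conventional dendritic cells were not separated from the monocyte or macrophage-like cluster, where 3 of their markers also reached 4-fold in at least 5% of barcodes. Natural killer cells were not separated from the T-like cluster, whose 10 leading genes included Nkg7 and Il2rb.

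For each class with at least 50 barcodes in every library, UMIs were summed per library and expressed as CPM of the class total. With 1 library per group there is no replicate error and no test: no p-value and no count of changed genes is given. Log2 ratios carry exact conditional binomial intervals, CPM exact Poisson intervals, shares exact Clopper-Pearson intervals and list medians intervals from 1000 Poisson redraws, all at 95% and all for counting error alone. In ratios, counts under 3 were set to 3, while the interval uses the counts as they are. A gene at 0 in a library has a ratio against 3 counts, and the lower limit of its interval can lie below that ratio. Gene lists, 40 in number, were fixed before the data were examined. A list member was measured with at least 20 UMIs over the 3 libraries in a class, and a list needed 5 measured members. For each list the members at least 1.5-fold higher or lower were counted, and the median was placed among 10000 random lists matched on mean expression in 20 bins, as a description of these libraries. Shares of barcodes with a UMI and genes per barcode were also computed after thinning each barcode to 1000 UMIs, with shallower barcodes left out.

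Named genes were chosen by a rule fixed before the data were examined. For the flox/flox library, genes were ranked by the smaller of their ratios against both other libraries, where both had the same sign. For wt/flox the ratio over wt/wt was used. A gene needed 50 UMIs where it had to be higher, and mitochondrial, ribosomal, predicted, Xist and Y-linked genes were left out. To keep out free RNA, a gene was checked in the library where its CPM in the class was highest. There its CPM had to reach 0.25 of its highest CPM in any other class with at least 50 barcodes. Erythroid-like barcodes, 40 in wt/wt and 7 in flox/flox, were thus compared in wt/flox alone. For classes other than hepatocyte-like it also had to reach 2 times the CPM of hepatocyte-like barcodes. The rule's wording left open whether the second condition replaces the first, and both were applied. The 12 highest and 12 lowest genes are named in hepatocyte-like barcodes, 10 and 10 in macrophage-like barcodes and 5 and 5 elsewhere, besides Adar, Ifih1, Grn, Egfr, Sort1 and Alb and up to 4 members per list. Values of 3 genes chosen in this way are not reported here. Genes were placed on mm10 with GENCODE vM21, which holds the IDs of 32158 of 32285 features. The list genes Mx1, Mx2, Sting1, Mb21d1, C5, Cyr61 and Ctgf are absent by symbol. Counts of close paralogs, such as the major urinary proteins, the Oas1, Cyp2a, Gbp, H2-Q, Ifi27l2, Orm, Serpina3, Tgtp and immunoglobulin genes, can be split between copies and are uncertain.

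Free hepatocyte RNA in another class was estimated as the median, over hepatocyte markers, of their level there relative to hepatocyte-like barcodes of the same library. This estimate reads any hepatocyte RNA in a barcode, from free RNA or from a joined hepatocyte, as free. The estimated share of UMIs in wt/wt, wt/flox and flox/flox was 47.4%, 46.3% and 38.1% in Kupffer-like barcodes. It was 63.4%, 64.8% and 52.6% in T-like barcodes and 58.6%, 60.4% and 57.8% in endothelial-like barcodes. The subtraction was tried as an alternative. RNA of each other class with at least 50 barcodes in every library made up at most 0.184% of hepatocyte-like UMIs. The share of erythroid-like RNA was not estimated.

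The steps were tested on simulated counts with 200 changed genes. These were Poisson draws from a single pooled profile per class, without differences between animals or preparations. They check the steps for counting error alone and not the naming of genes between single libraries. In hepatocyte-like barcodes, with 11356 genes, intervals held the true ratio for 95.8% of unchanged genes and for 84.8% of genes changed 4-fold. In macrophage-like barcodes, with 8772 genes, these shares were 96.9% and 100%. All 12 and 10 genes named in each direction were simulated changes. A simulated list with 34 members changed 2-fold had a median of 1.00 in hepatocyte-like and 0.96 in macrophage-like barcodes. Simulated free RNA of 30% and 60% in Kupffer-like barcodes was found as 29.7% and 60.3%. The RNA mixed in had the same profile as that used to estimate it, and the class's own counts of hepatocyte markers were removed beforehand.

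The alternatives tried were minimums of 1000 and 2000 UMIs, mitochondrial limits of 20% and 60%, resolutions of 0.5 and 2, scaling by TMM (edgeR 4.0.16 under R 4.3.3), by median of ratios (DESeq2 1.42.0) and by totals without mitochondrial genes, means over barcodes, thinning, subtraction of free RNA, 100 UMIs per list member, and other denominators of shares. An alternative value is compared with the counting interval of the reported value, and a direction is called where that interval excludes 0; both rules, and a minimum per library of 50 barcodes for genes and lists and of 3 for shares in an alternative, were set after the data were seen. Also chosen after the data were seen were the lists described outside hepatocyte-like barcodes, removal of the 8% of barcodes with the highest doublet score, and the restriction to hepatocyte-like barcodes rich in the nuclear transcripts Malat1 and Neat1. Plots were drawn with matplotlib 3.10.9.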

Results

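Single-cell RNA profiles were collected from livers of Ifih1-deficient, Alb-Cre-positive male mice with 3 Adar1 genotypes. ADAR1 edits double-stranded RNA, and MDA5, the product of Ifih1, senses it. Each genotype, wt/wt, wt/flox and flox/flox, had 1 library, so that no difference has a replicate check and all intervals cover counting error alone. Each library held 10000 barcodes, with 9744380 UMIs in wt/wt, 10067929 in wt/flox and 10756790 in flox/flox. Kept barcodes had a median of 853, 898.5 and 932 UMIs and of 4.86%, 4.07% and 7.05% mitochondrial UMIs in wt/wt, wt/flox and flox/flox.

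Transcripts of the targeted gene came before every other comparison, as a check of the labels. Adar (ENSMUSG00000027951, mm10 chromosome 3, 89715022 to 89753446) was highest in hepatocyte-like barcodes of the library labelled flox/flox, against its label. Its level there was 35.4 CPM (95% counting interval 31.4 to 39.7; 292 UMIs), against 10.3 CPM (8.22 to 12.9; 81 UMIs) in wt/wt and 17.3 CPM (14.4 to 20.6; 124 UMIs) in wt/flox. The log2 ratio was 1.77 (1.41 to 2.15) over wt/wt and 1.03 (0.72 to 1.35) over wt/flox, and that of wt/flox over wt/wt was 0.74 (0.33 to 1.16). In all barcodes of other classes Adar stood at 22.1, 29.1 and 61.4 CPM in wt/wt, wt/flox and flox/flox. A 3' tag outside the deleted part of the gene would not show the deletion, and the labels do not give the floxed exons, so that the level does not check the label. Every direction given for the libraries labelled wt/flox and flox/flox rests on those labels, and Adar was above wt/wt in both. Ifih1 (ENSMUSG00000026896, chromosome 2, 62595798 to 62646255), which all 3 genotypes lack, had 0, 1 and 0 UMIs among all kept barcodes, with upper limits of 0.383, 0.558 and 0.349 CPM in wt/wt, wt/flox and flox/flox.

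Hepatocyte-like barcodes were compared because, by the labels, they are the class in which Alb-Cre acts on the floxed gene; the deletion itself was not seen in these data. Genes of the type I interferon response, the antiviral program that cells switch on after sensing interferon, were higher in the library labelled flox/flox than in both others. Their median log2 ratio was 2.42 (95% counting interval 2.02 to 2.61) over wt/wt, with 30 of 30 measured members at least 1.5-fold higher. Over wt/flox the median was 1.48 (1.33 to 1.67), with 28 of 30 members at least 1.5-fold higher and 0 lower. Among its members Ifi44 had log2 ratios of 7.46 (5.91 to 9.74) and 4.46 (3.85 to 5.15) over wt/wt and wt/flox, and Oasl2, of the oligoadenylate synthetase family, 5.04 (3.79 to 6.69) and 4.65. The lowest ratios among members were those of Stat2, a transducer of interferon signals, at 1.10 and 0.31, and of Bst2 (tetherin), at 0.94 and 0.43.

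Related immune lists were higher to a lesser degree. The interferon gamma list had medians of 1.07 (1.02 to 1.83) over wt/wt and 0.53 (0.24 to 0.60) over wt/flox, with 13 and 6 of 15 members at least 1.5-fold higher and 1 and 2 lower. Its guanylate-binding protein gene Gbp3 had log2 ratios of 4.21 and 4.67, Irf1 had 0.13 and -0.87, and Cd274 (PD-L1), with 1 UMI in flox/flox, had -1.30 (-8.38 to 0.08) and -2.32 (-9.31 to -1.17). The double-stranded RNA sensing list had medians of 1.06 (0.72 to 1.31) and 0.60 (0.44 to 0.79), with 7 and 6 of 11 members at least 1.5-fold higher. In it the nucleic acid sensor Zbp1 had ratios of 1.69 and 1.40, Dhx58 (LGP2) 1.32 and 1.12, and Mavs, the adaptor below MDA5, -0.17 and -0.26. MHC class I presentation had medians of 0.70 (0.57 to 0.85) and 0.44 (0.38 to 0.58), with 12 and 8 of 20 members at least 1.5-fold higher, among them the peptide transporter gene Tap1 at 1.02 and 0.69. MHC class II presentation had medians of -0.08 (-0.58 to 0.37) and 0.26 (-0.20 to 0.75) over 5 members. The type I interferon medians lay above 100% of random lists matched on expression, and so did those of double-stranded RNA sensing. The sensing list shares Ddx58, Dhx58, Zbp1 and Eif2ak2 with the type I interferon list and also holds Adar. It is therefore not a separate result.

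The series title names an axis of progranulin and the epidermal growth factor receptor. Grn (ENSMUSG00000034708, chromosome 11, 102430315 to 102437048), which encodes progranulin, stood at 78.5, 69.4 and 120 CPM in hepatocyte-like barcodes of wt/wt, wt/flox and flox/flox, a log2 ratio of 0.61 (0.47 to 0.76) over wt/wt and 0.79 (0.64 to 0.95) over wt/flox. Egfr (ENSMUSG00000020122, chromosome 11, 16752203 to 16918158) stood at 371, 231 and 580 CPM, a ratio of 0.64 (0.58 to 0.71) over wt/wt and 1.33 (1.25 to 1.41) over wt/flox. Sort1, a progranulin receptor, was near 5 CPM in each library, with 0.06 (-0.59 to 0.72) and -0.03 (-0.68 to 0.63), and no difference was detectable at this depth. The progranulin and EGFR list had medians of 0.37 (0.28 to 0.51) and 0.54 (0.44 to 0.70), with 6 and 6 of 16 members at least 1.5-fold higher and 2 and 1 lower. The EGFR ligand gene Btc had 2.08 and 1.80, the protease inhibitor gene Slpi 3.32 and 3.60, and Erbb3, another receptor of the EGFR family, -0.65 and -0.70. Feedback genes of the EGFR and MAPK pathway had medians of 0.40 (0.13 to 0.51) over wt/wt and -1.23 (-1.50 to -0.80) over wt/flox, with 3 and 1 of 12 members at least 1.5-fold higher and 1 and 8 lower. The cyclin gene Ccnd1 was higher over both, at 0.46 and 0.95, while the inhibitor gene Spry4 had -0.49 and -2.14.

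The genes named by the rule in hepatocyte-like barcodes of the library labelled flox/flox included several with other functions than interferon response. Oas1g, Oas1a and Usp18 are members of the type I interferon list and are not separate results. Cyp2a4, a steroid hydroxylase, stood at 1.02 CPM in wt/wt, 1.12 CPM in wt/flox and 88.0 CPM in flox/flox, with log2 ratios of 6.43 (5.44 to 7.65) and 6.30 (5.32 to 7.52). The carbonyl reductase gene Cbr3, with 2 and 3 UMIs in wt/wt and wt/flox, had 5.40 (4.11 to 9.05) and 5.28 (3.70 to 7.57). Xlr4a, on the X chromosome, was at 0 UMIs in wt/wt and wt/flox and, against a floor of 3 counts per library, 24.3-fold and 22.3-fold higher, with lower 95% limits of 4.27 and 4.15 in log2. Oas1g was likewise at 0 and 17.7-fold and 16.2-fold higher against that floor, with lower limits of 3.80 and 3.67. Spats2l had 4.81 (3.5038 to 8.47) and 3.95 (2.67 to 5.61), Oas1a 4.59 (3.65 to 11.49) and 3.72 (2.44 to 5.39), and the trypsin inhibitor gene Spink1 5.15 (3.84 to 8.79) and 3.02 (2.16 to 4.01), each with 1 or 2 UMIs in wt/wt. Usp18, a negative regulator of interferon signalling, had 3.57 and 2.89, Ifi27l2b 4.37 and 2.73, the lipid synthesis gene Gpat3 2.82 and 2.69, and the potassium channel gene Kcnt2 2.51 and 3.12.

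The genes named as lower in that library than in both others were led by Nr4a1. This immediate early nuclear receptor gene had log2 ratios of -2.55 (-3.42 to -1.77) over wt/wt and -3.32 (-4.17 to -2.57) over wt/flox. Bcl6, a transcriptional repressor, had -2.05 and -1.64, Srebf1, a regulator of fatty acid synthesis, -1.41 and -1.46, the nuclear receptor gene Ppard -1.40 and -1.83, Foxq1 -1.45 and -3.35, and the clock gene Cry1 -1.28 and -1.78. The other named genes were Abtb2 (-1.98 and -1.75), Dpy19l3 (-1.50 and -1.60), Zap70 (-1.47 and -1.45), Rtn4rl1 (-1.40 and -1.76), Arhgap6 (-1.35 and -1.37) and Lrfn3 (-1.31 and -1.61). In barcodes rich in nuclear transcripts, a setting added after the data were seen, Ppard had 0.08 over wt/wt.

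**Figure D1:**
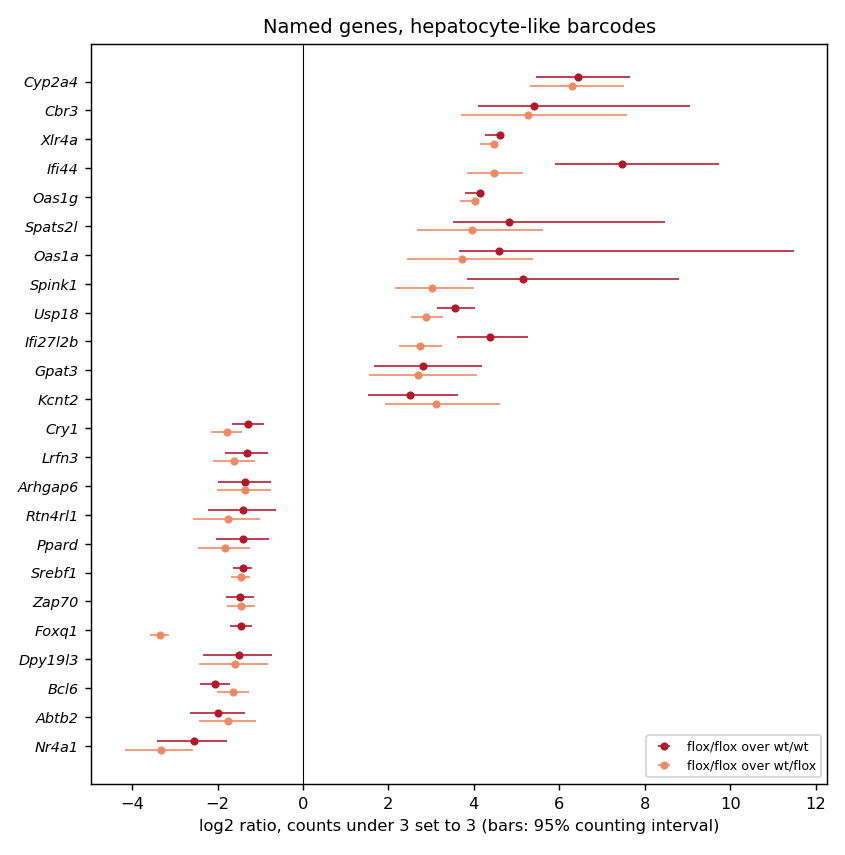
Log2 ratio of the library labelled flox/flox over wt/wt and over wt/flox for the genes named in hepatocyte-like barcodes; points are ratios with counts under 3 set to 3 and bars are 95% counting intervals, open to the right for Xlr4a and Oas1g, which had 0 UMIs in both other libraries. Ratios over wt/wt span -2.55 for Nr4a1 to 7.46 for Ifi44.

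Hepatocyte programs other than immune genes were read as lists as well. The fetal, progenitor and injury list had medians of 1.06 (0.58 to 1.19) over wt/wt and 0.59 (0.20 to 1.01) over wt/flox, with 8 and 8 of 15 members at least 1.5-fold higher and 0 and 2 lower. It was led by Spp1 (osteopontin), at 4.08 (3.65 to 4.55) and 2.01 (1.77 to 2.26), and Ly6d, at 0 UMIs in wt/wt. With a minimum of 1000 UMIs a cluster of bile duct cells (cholangiocyte-like) had 6, 8 and 23 barcodes in wt/wt, wt/flox and flox/flox. The main clustering separated no such class, and whether these barcodes bear on Spp1 and this list was not tested. The chemokine and cytokine list, which also holds Spp1, had 0.60 and -0.11 over 14 members. In it Ccl5 had 2.44 and 2.80 and Cxcl1 -0.49 and -2.17. Ccl5 was the leading gene of the T-like cluster by fold. T-like RNA was an estimated 0%, 0% and 0.0522% of hepatocyte-like UMIs in wt/wt, wt/flox and flox/flox. The Ccl5 ratios are not told apart from this free RNA. Lysosomal genes had 0.41 (0.30 to 0.48) and 0.45 (0.37 to 0.56), with 8 and 8 of 25 members at least 1.5-fold higher and 0 lower. Complement genes had 0.35 and 0.16 over 18 members. The acute phase list had 0.33 and 0.01 over 28 members, with Lcn2 (lipocalin) at 3.21 and 1.91 and Fgb (fibrinogen) at -0.17 and -0.45. Urea cycle and amino acid genes had -0.38 (-0.43 to -0.30) and 0.04 (-0.05 to 0.12), with 0 of 24 members higher and 7 lower over wt/wt, among them the glutaminase gene Gls2 at -0.75 and -0.52. Alb (albumin) had -0.23 and 0.21. In barcodes rich in nuclear transcripts the acute phase list had -0.24 and the chemokine list -0.18 over wt/wt, and complement had -0.17 over wt/flox. Alb had 0.12 over wt/wt with a minimum of 2000 UMIs.

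Metabolic and stress lists were read in the same barcodes. The unfolded protein and integrated stress list had 0.44 over wt/wt and -0.02 over wt/flox, with Fgf21 at 1.54 and 3.53 and Sdf2l1 at -0.31 and -1.96. Fatty acid oxidation had -0.23 and -0.10, with Acaa1b at -1.76 and -1.23. Lipogenesis had -0.09 and 0.07, with the fatty acid transporter gene Cd36 at 2.64 and 2.56. Sterol synthesis had 0.05 and 0.25, with Hmgcs1 at 0.72 and 1.28. Bile acid genes had 0.15 and 0.12, gluconeogenesis 0.14 and 0.23, coagulation 0.09 and 0.16, apolipoproteins -0.19 and -0.27, and cytochrome P450 and conjugation 0.10 and 0.12. In the last, Cyp2a5 had 1.54 and 1.72 and Cyp2c29 -0.73 and -0.85. Pericentral genes had -0.02 and 0.01 and periportal genes -0.12 and 0.17. The major urinary proteins had 0.03 and -1.13, with Mup20 at 1.27 and 0.81 and Mup1 at -0.80 and -2.44. The p53 list had 0.13 and 0.25, apoptosis and necroptosis 0.16 and -0.05 with the necroptosis effector gene Mlkl at 1.59 and 1.74, NF-kappaB targets -0.01 and -0.13, immediate early genes -0.03 and -0.42, and DNA replication and mitosis -0.10 and -0.16. Medians over wt/wt with a minimum of 2000 UMIs were 0.0367 for fatty acid oxidation, 0.0794 for apolipoproteins and 0.12 for periportal genes. In barcodes rich in nuclear transcripts fatty acid oxidation had 0.0543 and 0.15 over wt/wt and wt/flox, coagulation -0.22 over wt/wt, and sterol synthesis -0.0588 and immediate early genes 0.37 over wt/flox.

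Marker lists of other cell types were also read in hepatocyte-like barcodes. RNA of each other class with at least 50 barcodes in every library made up at most 0.184% of UMIs there. For genes that hepatocytes hardly express, such a share can still be much of the counts. In wt/wt, wt/flox and flox/flox it was 0.128%, 0.102% and 0.183% for Kupffer-like RNA. It was 0.0757%, 0.0335% and 0.123% for monocyte or macrophage-like, 0.132%, 0.151% and 0.184% for endothelial-like and 0.140%, 0.110% and 0.107% for stellate or fibroblast-like RNA. The medians that follow are not told apart from differences in this free RNA. Resident Kupffer genes had medians of 0.56 over wt/wt and 0.48 over wt/flox, lipid-associated macrophage genes 0.40 and 0.41, inflammatory macrophage genes 0.49 and -0.23, and alternative macrophage genes 0.27 and 0.04. Sinusoidal endothelial genes had 0.21 and 0.47, endothelial capillarisation genes 0.72 and 0.05, and collagen genes -0.08 and -0.04. Fewer than 5 members of the monocyte-derived list, of the lymphocyte cytotoxicity list and of the ADAR family list were measured there. Different clusters held most hepatocyte-like barcodes of each library: clusters 4, 6, 2 and 7 in wt/wt, 5, 2, 6, 4 and 7 in wt/flox, and 3, 1 and 7 in flox/flox. With a minimum of 2000 UMIs per barcode the type I interferon median was 1.28 over wt/wt and 0.59 over wt/flox.

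Shares of barcodes with a UMI had the same order. Ifit1, an interferon-induced gene, was seen in 0.618%, 1.28% and 6.61% of hepatocyte-like barcodes of wt/wt, wt/flox and flox/flox. After thinning to 1000 UMIs the shares were 0.926%, 1.21% and 6.5015%, with 5876, 5032 and 4927 barcodes left out. As a background, the T-cell gene Cd3e was seen in 0.0121%, 0% and 0.0128% of these barcodes, whose median depths were 825, 862 and 904 UMIs. In T-like barcodes, with median depths of 988, 964 and 967 UMIs, Cd3e was seen in 26.7%, 23.9% and 26.0%. The Kupffer cell gene Clec4f was seen in 83.2%, 76.5% and 78.7% of Kupffer-like barcodes. In hepatocyte-like barcodes Clec4f was seen in 0.388%, 0.313% and 0.472%, a higher background than that of Cd3e. Median genes per hepatocyte-like barcode were 510, 535 and 546, and 600, 603 and 598 after thinning.

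The library labelled wt/flox was set against wt/wt; that 1 Adar1 allele was lost in it was not seen in these data. In hepatocyte-like barcodes the type I interferon list was higher in wt/flox, with a median log2 ratio of 0.70 (0.47 to 0.81) and 16 of 30 members at least 1.5-fold higher and 0 lower. The most distinct genes had other functions: the metallothionein genes Mt2 and Mt1, which bind heavy metals, had log2 ratios of -4.42 (-4.60 to -4.24) and -3.69 (-3.76 to -3.62), at 811 against 37.9 CPM and 3232.2 against 251 CPM. Cish, a feedback inhibitor of cytokine signalling, was higher at 4.48 (3.80 to 5.26), as were Myc at 3.30 (2.73 to 3.92), the retinoic acid hydroxylase gene Cyp26a1 at 3.29 (2.69 to 3.95), the transcription factor gene Onecut1 at 2.63 and the acute phase gene Orm2 at 2.40. Also lower were Rgs16 at -3.63, Phf11c at -3.47 and the stress gene Ddit4 at -3.38. The flox/flox library lay near wt/wt for Mt1, at -0.07, and for Mt2, at 0.25.

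Lists set wt/flox apart from wt/wt in several hepatocyte programs. Major urinary proteins had a median of 1.40 (1.31 to 1.46), with 10 of 11 members at least 1.5-fold higher, and EGFR and MAPK feedback genes 1.33 (1.03 to 1.77), with 9 of 12. The unfolded protein and integrated stress list had 0.69 (0.59 to 0.74), with 12 of 21 members higher and 5 lower, and the interferon gamma list 0.64 (0.52 to 0.94), with 8 of 15 higher. NF-kappaB targets had 0.46, chemokines 0.56, acute phase genes 0.36, immediate early genes 0.35, fetal and injury genes 0.35, MHC class I genes 0.25, complement 0.24, pericentral genes 0.24, apolipoproteins 0.20 and double-stranded RNA sensing 0.20. Urea cycle genes had -0.40 (-0.42 to -0.35), sterol synthesis -0.23, p53 genes -0.21, the progranulin and EGFR list -0.20, lipogenesis -0.18, bile acid genes -0.13 and fatty acid oxidation -0.10. Grn had -0.18 (-0.35 to -0.00), Egfr -0.69 (-0.77 to -0.60) and Alb -0.44. With a minimum of 2000 UMIs Egfr had 0.23, Grn 1.18, sterol synthesis 0.58, lipogenesis 0.23, the progranulin and EGFR list 0.21, pericentral genes -0.16 and fetal and injury genes -0.0579.

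Macrophage-like barcodes were compared because the series title names crosstalk of hepatocytes and macrophages. Type I interferon genes were higher there too in the library labelled flox/flox, with medians of 1.59 (1.29 to 1.78) over wt/wt and 0.92 (0.67 to 1.06) over wt/flox and 27 and 23 of 31 members at least 1.5-fold higher. Lipid-associated macrophage genes had 0.45 (0.25 to 0.96) and 0.41 (0.13 to 0.64), led by Gpnmb at 2.19 (0.97 to 3.69) and 3.62 (2.18 to 5.54) and by the lipid receptor gene Trem2 at 1.68 (0.66 to 2.87) and 1.17 (0.45 to 1.93). Lysosomal genes had 0.22 (0.11 to 0.31) and 0.46 (0.32 to 0.49), and Ctss (cathepsin S) 0.75 and 0.52. Grn stood at 955, 895 and 1123.3 CPM in wt/wt, wt/flox and flox/flox, a ratio of 0.23 (0.06 to 0.41) over wt/wt and 0.33 (0.18 to 0.48) over wt/flox. In Kupffer-like barcodes alone it stood at 1361.5, 1552.3 and 1983.5 CPM, with 0.54 (0.36 to 0.73) and 0.35 (0.19 to 0.52), and in monocyte or macrophage-like barcodes at 152, 214 and 422 CPM, with 1.47 (0.80 to 2.21) and 0.98 (0.58 to 1.38). After subtraction of free hepatocyte RNA the Grn ratios over wt/wt and wt/flox were 0.0417 and 0.0772 in macrophage-like, 0.34 and 0.16 in Kupffer-like, and 1.53 and 0.76 in monocyte or macrophage-like barcodes.

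Chemokine and immediate early lists had lower medians in macrophage-like barcodes of the same library. Chemokines and cytokines had medians of -0.44 (-0.71 to -0.04) over wt/wt and -0.45 (-0.74 to -0.15) over wt/flox, with 6 and 3 of 17 members at least 1.5-fold higher and 7 and 7 lower, and with Il1b at -2.43 (-3.22 to -1.68) and -2.15 (-2.92 to -1.45). Immediate early genes, which also answer to tissue dissociation, had -0.33 (-0.64 to -0.00) and -0.41 (-0.68 to -0.23), with 2 and 0 of 15 members higher and 4 and 5 lower, and with Fos at -1.51 and -1.41 and Dusp1 at -1.79 and -1.27. Resident Kupffer identity had -0.29 (-0.48 to -0.21) and -0.11 (-0.23 to 0.05), with Clec4f at -0.48 and 0.10, and monocyte-derived identity 0.55 (0.41 to 0.86) and -0.41 (-0.51 to -0.12). The identity lists are read beside the mixture of the class, in which Kupffer-like barcodes made up 220 of 315, 298 of 562 and 291 of 599 macrophage-like barcodes. With at most 60% mitochondrial UMIs they made up 235 of 313, 323 of 562 and 388 of 599, so that this mixture is itself uncertain. The interferon gamma list had 0.29 and -0.40, with Cxcl9 at -1.31 and -1.08. MHC class I genes had 0.29 and 0.20, MHC class II genes 0.08 and 0.53, double-stranded RNA sensing 0.37 and 0.44, the progranulin and EGFR list 0.16 and 0.43, NF-kappaB targets -0.11 and 0.13, inflammatory macrophage genes -0.07 and 0.34, alternative macrophage genes -0.12 and -0.03, and DNA replication and mitosis 0.62 and 0.19.

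Other named macrophage-like genes were higher over wt/wt and over wt/flox, respectively, for the stem cell antigen gene Ly6a (3.42 and 2.09), Ifi213 (2.40 and 1.24), Ms4a7 (1.75 and 2.06), the interferon regulator Irf7 (1.74 and 1.77), Oasl2 (1.68 and 2.03), Ptafr (1.47 and 1.58), Cd93 (1.13 and 1.69) and Mdfic (1.12 and 1.12). Lower were Cd207 (langerin, -2.40 and -1.77), Tnfaip2 (-0.92 and -0.81), the prostaglandin-degrading enzyme gene Hpgd (-0.84 and -0.80), Grk2 (-0.75 and -0.87), Junb (-1.01 and -0.64), Dmpk (-0.80 and -0.53), the iron exporter gene Slc40a1 (-0.70 and -0.60), Pou2f2 (-0.64 and -0.65) and Cggbp1 (-0.64 and -0.60). These values too are read beside the mixture of the class and are not differences within 1 cell type. Slc40a1, a marker of Kupffer cells, had -0.29 (-0.48 to -0.10) and -0.55 (-0.72 to -0.38) in Kupffer-like barcodes and 1.42 (0.30 to 2.79) and 1.10 (0.39 to 1.86) in monocyte or macrophage-like barcodes. Free hepatocyte RNA was an estimated 38.1% of Kupffer-like UMIs in flox/flox, against 47.4% in wt/wt and 46.3% in wt/flox. After its subtraction the type I interferon median in macrophage-like barcodes was 0.62 over wt/flox and the MHC class I median -0.00628.

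**Figure D2:**
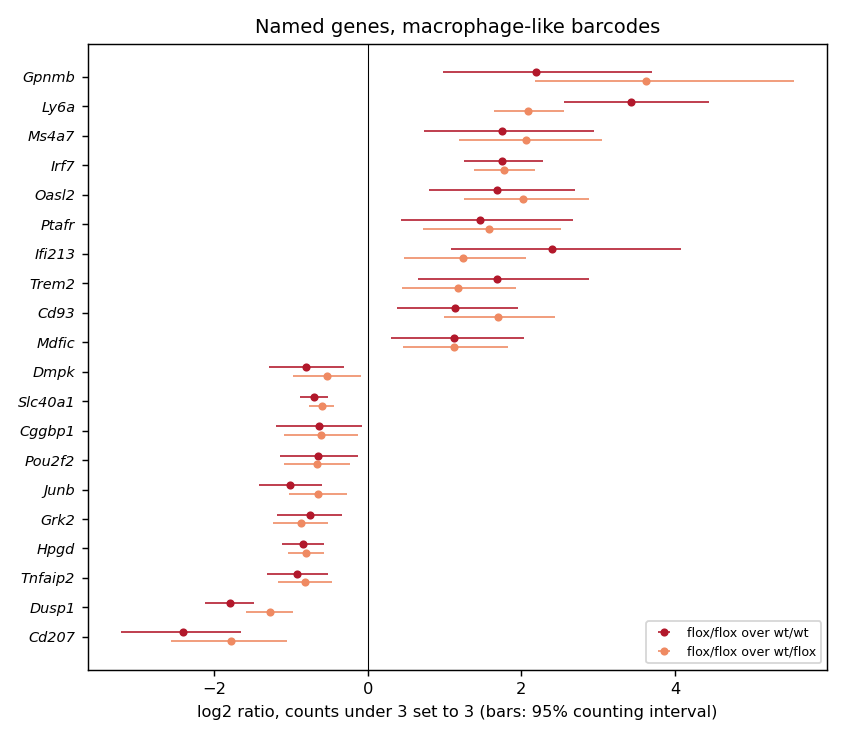
Log2 ratio of the library labelled flox/flox over wt/wt and over wt/flox for the genes named in macrophage-like barcodes; points are ratios and bars are 95% counting intervals. Ratios over wt/wt span -2.40 for Cd207 to 3.42 for Ly6a.

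Kupffer-like and monocyte or macrophage-like barcodes were also read apart. Dendritic cells were not separated from the latter class: 4 class II genes were among the 10 leading genes of its cluster, the dendritic markers Xcr1, Cd209a and Cst3 were at least 4-fold above other barcodes there, and only clustering with at least 2000 UMIs gave a conventional dendritic-like cluster, with 8, 9 and 16 barcodes in wt/wt, wt/flox and flox/flox. In Kupffer-like barcodes the type I interferon list had medians of 1.66 (1.38 to 2.02) over wt/wt and 0.94 (0.71 to 1.17) over wt/flox. Ly6a (4.18 and 2.23), Ms4a6b (2.48 and 1.86), Irf7 (2.31 and 1.99), Plac8 (2.14 and 2.15) and Tmem26 (1.296 and 1.83) were higher. Il1b (-2.15 and -2.08), Dusp1 (-1.72 and -1.27) and the class II genes H2-Eb1 (-2.04 and -1.65), H2-Ab1 (-1.70 and -1.24) and H2-Aa (-1.33 and -1.07) were lower. MHC class II presentation had -1.33 (-1.47 to -1.06) and -1.07 (-1.32 to -0.94), immediate early genes -0.57 and -0.59, chemokines -0.56 and -0.01, lysosomal genes 0.29 and 0.36, lipid-associated genes 0.43 and 0.44, DNA replication 0.85 and 0.07, inflammatory macrophage genes 0.19 and 0.80, and resident identity 0.07 and -0.07. The remaining Kupffer-like lists had 0.29 and -0.01 for interferon gamma, 0.18 and 0.27 for MHC class I, 0.53 and 0.53 for double-stranded RNA sensing, 0.20 and 0.36 for progranulin and EGFR, 0.01 and -0.24 for NF-kappaB, and 0.10 and -0.09 for alternative macrophages. At a clustering resolution of 0.5, where all macrophages form a single class, the class II median over wt/flox was 0.51 and Plac8 stood at -0.00225. H2-Ab1 over wt/flox had 0.0261 with a minimum of 1000 UMIs and 0.0505 with at most 60% mitochondrial UMIs, and at resolution 0.5 H2-Ab1 had 0.0122 and 0.55, H2-Aa 0.12 and 0.54 over wt/wt and wt/flox, and H2-Eb1 0.51 over wt/flox. The direction of H2-Ab1 and H2-Aa, and that of H2-Eb1 over wt/flox, is not firm.

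In monocyte or macrophage-like barcodes the type I interferon list had medians of 1.13 (0.81 to 1.37) and 0.81 (0.60 to 1.19) over wt/wt and wt/flox. Lysosomal genes had 0.62 (0.41 to 0.86) and 0.66 (0.51 to 0.82), with 14 and 14 of 24 members at least 1.5-fold higher and 0 lower, and the cathepsin genes Ctsd (1.70 and 1.83) and Ctsb (1.36 and 1.20) were named higher with Ms4a7 (1.34 and 2.73), Tgfbr1 (2.31 and 1.29) and Slc43a2 (1.29 and 1.28). Hbb-bs, a haemoglobin gene with 1 UMI in flox/flox, had -6.61 (-13.51 to -5.67) and -5.09 (-12.00 to -4.16), and erythroid-like barcodes too were fewest in that library. It was highest in wt/wt, at 662 CPM, where the rule did not compare it with the 40 erythroid-like barcodes. Ratios of Hbb-bs here and below are not told apart from free red cell RNA. Coro1a (-0.50 and -0.60) was lower, while the intervals of Lsp1 (-0.57 and -0.30) over wt/flox, of Btg1 (-0.34 and -0.34) over wt/wt and of Vim (-0.25 and -0.22) over both include 0. MHC class II genes had 0.19 and 1.03, lipid-associated genes 0.45 and 0.76, alternative macrophage genes 0.60 and 0.91, resident Kupffer genes 0.26 and 0.66, and monocyte-derived identity -0.13 and -0.56. With a minimum of 1000 UMIs the lipid-associated median was -0.19 over wt/wt and -0.0253 over wt/flox and the resident median -0.54 over wt/flox. With at most 60% mitochondrial UMIs they were -0.31, -0.13 and -0.32, and the alternative macrophage median over wt/flox was -0.0709, so that the direction of these 3 lists is not firm.

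For wt/flox over wt/wt, macrophage-like barcodes had a type I interferon median of 0.44 (0.30 to 0.80) and a monocyte-derived identity median of 1.05 (0.76 to 1.19), with 13 of 19 members at least 1.5-fold higher and 0 lower. The monocyte genes Ccr2 (1.92), Cx3cr1 (1.66), Emb (1.59), F13a1 (1.54) and Ifitm6 (1.48) were highest, beside a share of Kupffer-like barcodes that was 298 of 562 against 220 of 315. Ddit4 (-2.38), Jdp2 (-2.19), the lipopolysaccharide co-receptor gene Cd14 (-1.68), Vcam1 (-1.62) and Plekhm2 (-1.43) were lowest. Within Kupffer-like barcodes the interferon median was 0.65 (0.35 to 0.90) and Ddit4 (-3.61), Fkbp5 (-2.16), Jdp2 (-1.80), Cd14 (-1.72) and Vcam1 (-1.32) were lowest, with Lcp2 (1.71), Zeb2 (1.21), C3ar1 (1.17) and Nfam1 (1.10) highest. In monocyte or macrophage-like barcodes the interferon median was 0.07 (-0.39 to 0.34), Ccr2 (1.39) and Cx3cr1 (1.26) were again high with Tmcc1 (1.36), Ifi203 (1.27) and Trim30a (1.24), and Ccl5 (-2.41), Hbb-bs (-1.51), H2-Eb1 (-1.14), Irf8 (-1.04) and Cst3 (-0.94) were low.

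In the remaining cell classes the type I interferon list was again higher in the library labelled flox/flox. In endothelial-like barcodes its medians were 2.13 (1.41 to 2.28) over wt/wt and 0.99 (0.84 to 1.497) over wt/flox, with 23 and 22 of 25 members at least 1.5-fold higher. In T-like barcodes they were 1.53 (1.01 to 1.71) and 1.06 (0.84 to 1.35), with 18 and 19 of 25 members higher. Stellate or fibroblast-like barcodes had 1.90 (1.48 to 2.34) and 0.99 (0.80 to 1.46), plasmacytoid dendritic-like barcodes 0.97 (0.64 to 1.29) and 1.37 (1.02 to 1.73), plasma-like barcodes 1.23 (0.78 to 1.75) and 0.88 (0.43 to 1.44), and neutrophil-like barcodes, with 7 members measured, 1.13 (0.47 to 2.06) and 1.56 (0.72 to 2.15). Over wt/wt the wt/flox library had medians of 0.50 in endothelial-like, 0.69 in stellate or fibroblast-like, 0.16 in T-like, 0.31 in plasma-like, -0.09 in neutrophil-like and -0.46 in plasmacytoid dendritic-like barcodes. Free hepatocyte RNA was an estimated 63.4%, 64.8% and 52.6% of T-like UMIs and 58.6%, 60.4% and 57.8% of endothelial-like UMIs in wt/wt, wt/flox and flox/flox. After its subtraction the T-like median over wt/wt was 0.63. In the same order the estimated share was 77.0%, 78.5% and 72.1% in neutrophil-like and 61.4%, 64.1% and 50.5% in plasma-like barcodes. It was 53.9%, 56.4% and 48.4% in plasmacytoid dendritic-like and 50.7%, 51.8% and 47.6% in stellate or fibroblast-like barcodes. The medians of these classes are given without subtraction and are not told apart from free hepatocyte RNA.

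**Figure D3:**
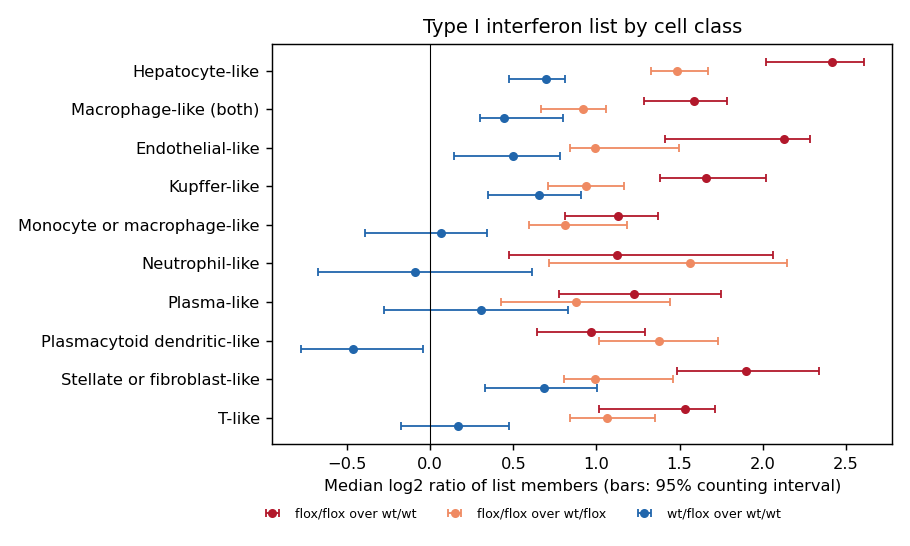
Median log2 ratio of measured type I interferon list members per cell class for the 3 comparisons of libraries; points are medians and bars are 95% counting intervals. Medians of flox/flox over wt/wt span 0.97 in plasmacytoid dendritic-like to 2.42 in hepatocyte-like barcodes.

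Genes named by the rule, some of them members of the type I interferon list, were read in these classes with class I and identity genes. Endothelial-like barcodes of the library labelled flox/flox had higher Ly6a (3.18 and 1.41 over wt/wt and wt/flox), Ifi44 (2.83 and 2.37), Rsad2 (viperin, 2.74 and 1.60), Xdh (1.54 and 2.18) and Sgms1 (0.97 and 2.14), and lower Ltbp4 (-1.61 and -1.50), Sox18 (-1.45 and -1.35), the tight junction gene Cldn5 (-1.44 and -1.40), Slc39a8 (-1.08 and -1.24) and Nid1 (-1.05 and -1.13). Their MHC class I median was 0.41 and 0.38, sinusoidal identity 0.05 and -0.05, and capillarisation -0.28 and 0.32. MHC class II had 1.34 (0.83 to 2.13) and 1.86 (1.26 to 2.55) over 5 members, and -1.38 and -0.21 with a minimum of 1000 UMIs. T-like barcodes had higher Ifi213 (2.52 and 1.61), Ifi27l2a (1.84 and 1.34), Trim30a (1.53 and 1.37), Samd9l (1.29 and 1.51) and the killer cell receptor gene Klrd1 (1.23 and 1.27), and lower Dusp2 (-1.24 and -0.61). For Ltb (-0.36 and -0.31), Tspo (-0.21 and -0.14), Tubb5 (-0.16 and -0.14) and Chd3 (-0.14 and -0.16) no difference was detectable at this depth. T-like MHC class I had 0.18 and 0.26, and -0.12 over wt/flox after subtraction of free hepatocyte RNA, and cytotoxicity and exhaustion had 0.27 and 0.24. No natural killer-like cluster was named in any setting, and Nkg7 and Il2rb were among the leading genes of the T-like cluster beside Cd3e and Cd3d. T-like values here and below, shares included, are not told apart from a mixture of T and natural killer cells. Stellate or fibroblast-like barcodes had higher Ly6a (5.65 and 2.45, 3 UMIs in wt/wt), Ifi27l2a (2.77 and 0.99), Postn (1.47 and 1.55), Ly6e (1.32 and 1.40) and Clic4 (0.92 and 0.86) and lower Fgfr2 (-0.93 and -1.30) and the retinol-storing enzyme gene Lrat (-0.71 and -1.31), with Nfib (-0.62 and -0.49) and Gnai2 (-0.55 and -0.47) lower than in wt/wt alone and Id3 (-0.60 and -0.88) than in wt/flox alone. Their collagen genes stood at 0.12 and 0.10 and their MHC class I genes at 0.29 and 0.19.

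The plasma-like class, with 559 barcodes, is mixed: clustering at resolution 2 gave a B-like cluster of 494 and a plasma-like cluster of 65 barcodes. Plasma-like barcodes of that library had higher Ly6c2 (3.45 and 2.45), Iglc1 (3.83 and 3.85), Hist1h2ap (2.96 and 2.33) and Ifi27l2a (1.72 and 1.99), and Slpi was at 0 UMIs in wt/wt and 2.54 over wt/flox. Cd79a (-0.81 and -0.31) and H2-Ab1 (-0.71 and -0.21) were lower than in wt/wt alone, and Btg1 (-0.42 and -0.44) and Ly6d (-0.32 and -0.57) than in wt/flox alone. For Mef2c (-0.29 and -0.22) no difference was detectable at this depth, and the MHC class I median was -0.06 and 0.28. Plasmacytoid dendritic-like barcodes had Mctp2 (0.92 and 1.17), Eif3e (0.87 and 1.12), Itga4 (0.85 and 0.90) and Ikzf1 (0.84 and 1.49) higher than wt/flox, with intervals over wt/wt that include 0, and a class I median of 0.29 and 0.30. The genes named lowest there were Lgals1 (-0.42 and -0.37), Ly6d (-0.38 and -0.43), Tyrobp (-0.20 and -0.14) and Bst2 (-0.14 and -0.04), of which only Ly6d over wt/flox had an interval that excludes 0. Neutrophil-like barcodes had higher Ngp (0.89 and 2.46), while no difference was detectable at this depth for Srgn (0.32 and 0.21), Retnlg (0.32 and 0.13) and Actb (0.11 and 0.18). Lower there were Dusp1 (-1.03 and -0.91), S100a11 (-0.99 and -0.92), S100a9 (-0.25 and -0.14) and, over wt/flox alone, Il1b (-0.47 and -0.72). S100a6 had -0.21 and -0.16 and S100a8 0.14 and 0.24, and the class I median was 0.47 and 0.45.

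Between wt/flox and wt/wt, the retinoic acid hydroxylase gene Cyp26b1 was higher in endothelial-like (3.05) and stellate or fibroblast-like (3.58) barcodes of wt/flox. Endothelial-like barcodes also had Ednrb (4.10), Ly6a (1.77), Col13a1 (1.25) and Lpar6 (1.21) higher and Shank3 (-1.80), Gja4 (-1.75), Aopep (-1.58), Rhob (-1.47) and Pcdh17 (-1.46) lower. T-like barcodes had the chemokine gene Xcl1 (1.41), Sept7 (1.32), Cd3g (1.16), Mndal (0.99) and Cxcr6 (0.76) higher and Evl (-1.35), Nop53 (-1.08), Txnip (-1.03), Ctsw (-1.03) and the interleukin receptor gene Il7r (-1.02) lower. In plasma-like barcodes the immunoglobulin genes Ighg2c (6.09, 3 UMIs in wt/wt), Ighg2b (5.01, 2 UMIs in wt/wt) and Iglc2 (2.77) were higher, with Ighg1, at 0 UMIs in wt/wt, and Manf (1.84), while Crip1 (-1.06), Tsc22d3 (-0.94), H2-D1 (-0.70), Cd74 (-0.65) and Ly6e (-0.51) were lower. Stellate or fibroblast-like barcodes had Gatm (0.95), Hs3st3b1 (0.80), Slmap (0.75) and Zeb2 (0.62) higher and Cebpd (-1.28), Nfkbia (-1.26), Hspg2 (-1.18), Klf2 (-1.14) and Crip2 (-1.08) lower.

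Cell class shares were compared to ask which liver cells differ in number between the genotypes. Macrophage-like barcodes made up 3.19% (exact Clopper-Pearson interval 2.85 to 3.55), 5.67% (5.22 to 6.14) and 6.13% (5.66 to 6.62) of kept barcodes in wt/wt, wt/flox and flox/flox. Monocyte or macrophage-like barcodes alone made up 0.962%, 2.66% and 3.15%, and Kupffer-like barcodes 2.23%, 3.00% and 2.98%. This split is not firm. With at most 60% mitochondrial UMIs it gave 78, 239 and 211 monocyte or macrophage-like and 235, 323 and 388 Kupffer-like barcodes. The monocyte or macrophage-like share was then highest in wt/flox, as with a minimum of 1000 UMIs (65, 197 and 182 barcodes). It stayed highest in flox/flox with at most 20% mitochondrial UMIs, at resolution 2 and without high doublet scores. T-like barcodes made up 3.33%, 5.15% and 6.03%, and plasmacytoid dendritic-like barcodes 0.557%, 0.998% and 1.71%. Endothelial-like barcodes were fewer in the library labelled flox/flox, at 4.53% (4.12 to 4.95), 4.93% (4.51 to 5.37) and 2.11% (1.83 to 2.41), as were stellate or fibroblast-like barcodes at 1.94%, 1.48% and 1.01%. Hepatocyte-like barcodes made up 83.5%, 74.0% and 80.2%, neutrophil-like 0.952%, 1.89% and 0.665%, plasma-like 1.37%, 2.55% and 1.75%, and erythroid-like, which red cell lysis can set, 0.405%, 2.91% and 0.0716%.

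The low-speed spin and the Percoll step bear on every share. Among barcodes outside the hepatocyte-like class, macrophage-like barcodes made up 19.4%, 21.8% and 30.9%, T-like 20.2%, 19.8% and 30.4%, and endothelial-like 27.5%, 18.99% and 10.6%. Erythroid-like barcodes, whose number red cell lysis can set, made up 2.46%, 11.2% and 0.361% of this denominator. They lower the other shares most in wt/flox. The ratio of flox/flox to wt/wt in this measure was 1.59 (1.39 to 1.83) for macrophage-like, 1.501 (1.31 to 1.72) for T-like and 0.386 (0.326 to 0.457) for endothelial-like barcodes. The deposited lower edge of 727, 721 and 636 UMIs decides which small cells enter, and with a minimum of 2000 UMIs the log2 ratio of flox/flox to wt/wt was -0.60 for macrophage-like, -1.03 for Kupffer-like and -0.71 for T-like shares. These rest on few barcodes: 31, 31 and 11 in wt/wt and 58, 43 and 19 in flox/flox. At a minimum of 1000 UMIs, with 4 neutrophil-like barcodes in wt/wt and 10 in flox/flox, the log2 ratio of their shares was 1.00.

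**Figure D4:**
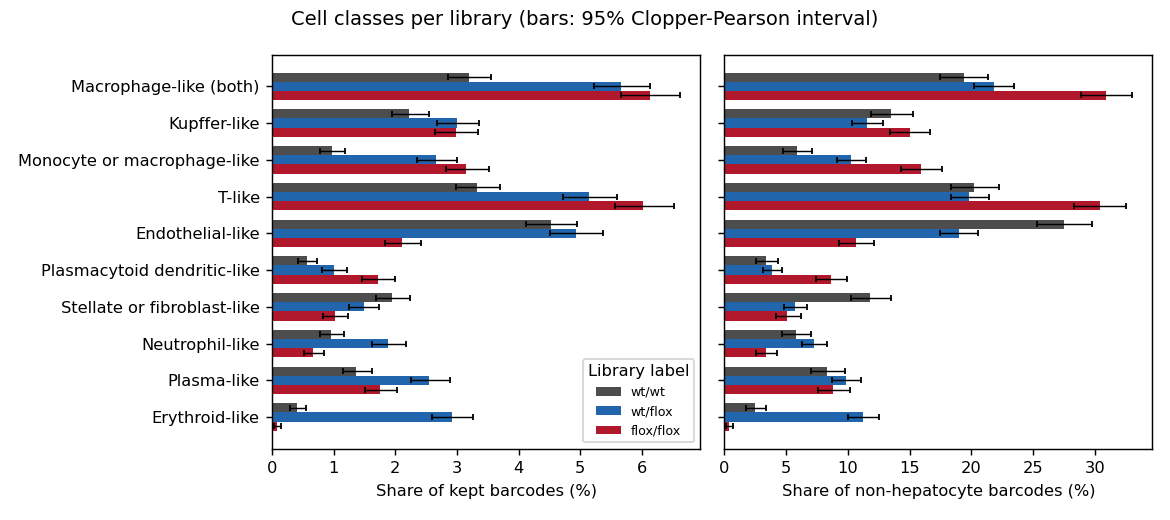
Share of kept barcodes per cell class in each library, with 95% Clopper-Pearson intervals. Monocyte or macrophage-like barcodes stand at 0.962%, 2.66% and 3.15% in wt/wt, wt/flox and flox/flox, and endothelial-like barcodes at 4.53%, 4.93% and 2.11%. With at most 60% mitochondrial UMIs the monocyte or macrophage-like share was highest in wt/flox.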

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

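Each group has 1 library, so no result met a rule for a closer look, and 3 patterns are weighed by choice. All tests were chosen after the result was seen, except thinning for hepatocyte-like barcodes and the smallest median after subtraction for the other classes.

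The type I interferon list was higher in hepatocyte-like barcodes of the library labelled flox/flox. Against free RNA of other classes, its summed CPM there was 0.338 (0.321 to 0.357) of that in Kupffer-like barcodes, above the bound of 0.25. Against a restriction to barcodes without a nucleus, the median in the cluster rich in Malat1 and Neat1 was 1.76 (1.57 to 2.25), above the bound of 0.6. For depth per barcode, it was 2.29 (1.88 to 2.55) after thinning, also above that bound. Thinning keeps the expected share of each gene in a barcode. Only the shallow barcodes left out and the equal weight of the others could move this median, so it cannot decide on depth. Genotype, animal, preparation and sequencing library cannot be told apart, since each genotype is a single library. The loss of Adar1 named by the design stays among the open explanations.

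The same list was higher in classes where Alb-Cre is not active, and free hepatocyte RNA was weighed. After its subtraction the smallest median, that of T-like barcodes, was 0.63 (0.33 to 1.10). The interval lies just above the bound of 0.3 but spans that of 0.6, which leaves that class open. The median was 1.497 (1.16 to 1.81) in Kupffer-like and 1.66 (1.18 to 2.23) in endothelial-like barcodes, which argues against free hepatocyte RNA as the whole of the pattern there. A response of these classes to signals from hepatocytes was not tested, and the confounding with the library remains.

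Adar was higher in the library where the label calls for its loss in hepatocytes. Against free RNA of other classes, at its estimated share this RNA brings 0.0225 (0.0149 to 0.0324) of the Adar CPM in hepatocyte-like barcodes, below the bound of 0.25, while the ratio of that CPM to the level in stellate or fibroblast-like barcodes, 0.301 (0.176 to 0.557), decided nothing alone. A general rise of interferon-responsive transcripts in all cells has the value it needs, a pooled log2 ratio of 1.11 (0.50 to 1.89) outside hepatocyte-like barcodes after subtraction, and stands as a hypothesis. A wrong library label stays open. A level not below wt/wt, here a ratio of 1.77 (1.41 to 2.15), can arise from it, and also where counts fall outside the deleted part of the gene. Such counts would hide a loss but would not by themselves raise the level.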

How the results depend on the processing

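No paired analysis was possible because each group has 1 library and the groups share only the replicate number 1. For the same reason no library could be left out in turn. The restriction to nuclear-transcript-rich barcodes and the removal of high doublet scores were chosen after the data were seen. Of 190 alternative values for share ratios 151 stayed within the counting interval, 31 moved and 8 reversed. For list medians these were 3580, 317 and 33 of 3930, and for named genes 4448, 229 and 15 of 4692. The type I interferon median kept its direction in every alternative: over wt/wt it spanned 1.28 to 2.60 in hepatocyte-like, 1.33 to 1.73 in macrophage-like, 1.44 to 2.18 in endothelial-like and 0.63 to 1.56 in T-like barcodes. Adar in hepatocyte-like barcodes over wt/wt spanned 1.44 to 2.28. Genes and lists needed 50 barcodes per library in a setting and share ratios 3, so that some share ratios rest on few barcodes. Resolution 0.5 had no monocyte class, and at resolution 2 the plasma share counts the B-like and plasma-like clusters. Few barcodes reach 2000 UMIs, 179 in wt/wt, 179 in wt/flox and 506 in flox/flox, so that the libraries are unevenly represented and values there rest on a small part of the data. The cause was not tested for any value that follows.

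In what follows, ff/ww is flox/flox over wt/wt, ff/wf flox/flox over wt/flox and wf/ww wt/flox over wt/wt, all as log2. With TMM scaling neutrophil S100a8 had -0.0074 (ff/wf). With free RNA subtracted it had -0.17. MHC class I (ff/wf) then had -0.0063 in macrophage-like, -0.11 in monocyte or macrophage-like and -0.12 in T-like barcodes. Type I interferon had 0.62 in macrophage-like (ff/wf) and 0.63 in T-like barcodes (ff/ww). With 100 UMIs per list member that list (ff/ww) had 1.83 in hepatocyte-like and 0.76 in T-like barcodes.

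With a minimum of 1000 UMIs, ff/wf values were 0.0201 for monocyte Btg1, 0.0261 for Kupffer H2-Ab1, -0.21 for endothelial MHC class II (ff/ww -1.38), -0.0253 for monocyte lipid-associated genes (ff/ww -0.19) and -0.54 for monocyte resident Kupffer genes (wf/ww 0.36). Shares (ff/ww) had -1.62 for endothelial, 1.16 for monocyte or macrophage, 1.00 for neutrophil (4 barcodes in wt/wt and 10 in flox/flox) and 0.34 for T-like barcodes. With at most 60% mitochondrial UMIs, ff/wf values were 0.0505 for Kupffer H2-Ab1, and in monocyte or macrophage-like barcodes -0.0709 for alternative, -0.13 for lipid-associated (ff/ww -0.31) and -0.32 for resident Kupffer genes (wf/ww 0.36).

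With a minimum of 2000 UMIs, hepatocyte-like ff/ww values were 0.12 for Alb, 0.0794 for apolipoproteins, 0.0367 for fatty acid oxidation, 0.12 for periportal genes and 1.28 for type I interferon (ff/wf 0.59). The wf/ww values were 0.23 for Egfr, 1.18 for Grn, -0.0579 for fetal and injury genes, 0.23 for lipogenesis, -0.16 for pericentral genes, 0.21 for progranulin and EGFR and 0.58 for sterol synthesis. Shares (ff/ww) had 0.0125 for hepatocyte-like, -1.03 for Kupffer-like (wf/ww -0.15), -0.60 for macrophage-like and -0.71 for T-like barcodes, with 31, 31 and 11 barcodes in wt/wt and 43, 58 and 19 in flox/flox for the last 3.

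In nuclear-transcript-rich hepatocyte-like barcodes, ff/ww values were 2.28 for Adar, 0.0824 for Ppard, -0.24 for acute phase, -0.18 for chemokines, -0.22 for coagulation, 0.0543 for fatty acid oxidation (ff/wf 0.15) and 1.76 for type I interferon (ff/wf 1.27). The ff/wf values were -0.17 for complement, 0.37 for immediate early genes and -0.0588 for sterol synthesis (wf/ww 0.0217). At resolution 0.5 Kupffer-like ff/wf values were 0.54 for H2-Aa (ff/ww 0.12), 0.55 for H2-Ab1 (ff/ww 0.0122), 0.51 for H2-Eb1, 0.51 for MHC class II and -0.00225 for Plac8. That class then holds all macrophages. At resolution 2 alternative macrophage genes in macrophage-like barcodes had 0.0599 (wf/ww). Among non-hepatocyte barcodes shares had -1.37 for endothelial, 0.67 for macrophage and 0.59 for T-like (ff/ww), and -0.23 for Kupffer-like and -0.0289 for T-like barcodes (wf/ww). After thinning, Adar in hepatocyte-like barcodes had 2.22 (ff/ww) and type I interferon 0.44 (wf/ww).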

Other observations

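Antibody genes differed between the libraries in the plasma-like class, where clustering at resolution 2 gave 494 B-like and only 65 plasma-like barcodes. A few plasma cells can carry the counts of these genes. Ighg2c had 3 UMIs in wt/wt, 369 in wt/flox and 543 in flox/flox, Ighg2b 2, 175 and 218, and Ighg1 0, 88 and 90. The light chain gene Iglc2 had 84, 1037 and 1060 UMIs, while Iglc1 was high in flox/flox alone, with 58, 103 and 1225. Manf, an endoplasmic reticulum stress factor of secretory cells, had log2 ratios of 1.94 (1.19 to 2.78) for flox/flox and 1.84 (1.10 to 2.67) for wt/flox over wt/wt. Jchain was seen in 11.6% and Mzb1 in 15.4% of the class, which held 135, 253 and 171 barcodes in wt/wt, wt/flox and flox/flox. These genes were singled out here after their values were seen.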
